A study of Mus musculus with 6 samples.

How the data were processed

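Adherent cells of GM-CSF bone marrow cultures of Spic(igfp/igfp) mice were profiled after heme or vehicle at 6, 24 and 72 h, 1 array each (6 arrays). Per the labels' protocols, marrow was cultured in medium with 10% fetal calf serum and 20 ng/ml GM-CSF, and on day 6 received heme, at a dose typed as 80 µm and read here as µM, or the vehicle, 0.15 M NaCl with 10% NH4OH. Floating cells were discarded, adherent cells scraped, total RNA extracted on columns and biotin-labelled cRNA made with an Ovation PicoSL kit, per the labels' protocols. What the igfp allele carries, and whether the Spic probe set lies in an altered part of the gene, is not given in the sources used here.

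The authors deposited log2 expression values; per the submitters' processing notes and the series' design text, they were made by RMA with quantile normalization in ArrayStar. Versions of these tools are not given in the sources used here, and scanner values were not used here. Array medians ran from 5.34 to 5.45, so the deposited columns were not identical in distribution. Pairwise correlations across probe sets were 0.975 to 0.986. RMA summarises several probes into 1 value, and differences of dim probe sets are compressed towards 0.

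Of 35556 probe sets, 21789 named 1 gene in the platform annotation supplied, 1621 named several and 12146 were not listed; only the first kind was used for genes. Through gene identifiers, 21701 of them matched a current symbol of the GRCm38.p6 gene table, which updated 2 symbols. They covered 19936 genes. For the 1001 genes with several probe sets, the one with the highest mean over the 6 arrays was taken. Among named genes with several (Bnip3, Hspe1, Idi1, Me1, Psma5 and Rpl10a) differences of the probe sets had the same sign where either exceeded 0.1. Genes were kept where the highest of the 6 arrays reached the median of all values (5.37), which left 11516.

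Differences were heme minus vehicle on the log2 scale. At a single time point no test was possible with 1 array per group: genes at 2-fold or more were counted, and the median of a gene list was placed among 10000 random lists of its size matched on mean expression in 10 bins. Over the 3 time points, limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) was fitted on all 6 arrays with treatment and time as terms, leaving 2 residual degrees of freedom and a prior of 7.17, with Benjamini-Hochberg adjustment over the 11516 genes. Nothing in the labels says whether the arrays came from separate mice or cultures. Arrays of the same time deviated together from their treatment means, with correlations of 0.562, 0.215 and 0.531 at 6, 24 and 72 h. The highest with another time was 0.122. Deviations cancel within each treatment, which lowers the correlations with other times, so this contrast is no separate support for the pairing. The pairing rests on the time points in the labels. An interaction of treatment and time could not be tested, because no residual degrees of freedom are left.

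Gene lists, 33 in number, covered pathways and markers of cell types that such cultures can hold. Some genes are on several lists, among them Hmox1, Slc40a1, Slc48a1, Slc7a11, Me1 and Treml4, so results of different lists are not independent. Lists with at least 5 genes kept were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. The form with an estimated correlation uses the 2 residual degrees of freedom of the fit, so few lists can pass it whatever their correlation. The comparisons and their tests, the lists, the alternatives named below and the rule for named genes were fixed before the data were examined. Tests of explanations, of gene families and of time course, the splits, and some alternatives for lists and families came later. That rule took the 10 highest and 10 lowest genes at each time point and over the 3 time points (past the test there), 10 genes fixed by name, up to 4 members of each list with the largest mean difference, and the 5 largest vehicle changes in each direction; predicted genes and small RNAs were counted but not named. Members of a list outside it, such as Flvcr2, Siglec1, Slc25a37, Pparg and Pros1, were chosen after their values were seen, because counts were small.

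Alternatives were a second quantile normalization, median-centring, cyclic loess, other level filters, the mean of probe sets, an offset of 16 on the linear scale, thresholds of 1.5-fold and 4-fold, no time term, a variance trend, robust eBayes, and leaving out each time point. The limma step was tested on simulated data with the 11516 genes: of genes changed by 0.5, 1, 2 or 3 on the log2 scale, 7.8%, 89.4%, 99.9% and 100% were recovered, and without any change 0 genes were called in each of 20 runs. With changed genes present, 5.32% of calls were false. Each simulated change was the same at all 3 time points and genes varied independently. Recovery of changes that vary with time, or with correlated genes, was not measured. Python 3.11.15 with scipy 1.17.1 was used for tests of explanations.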

Results

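Gene expression was measured on 6 single-colour arrays, 1 for each combination of treatment and time. Bone marrow cells of mice with the genotype Spic(igfp/igfp), named for the gene of the transcription factor SPI-C, were grown with 20 ng/ml GM-CSF, a cytokine that expands macrophages and dendritic cells from marrow. After 6 days the cultures received 80 µM heme or vehicle, and the adherent cells were taken 6, 24 or 72 h later. The question, as far as the series states it, was whether heme acts on the development of iron-recycling macrophages. The table held log2 values for 35556 probe sets, and array medians ran from 5.34 to 5.45. The 6 h heme array had the highest median (5.45) and the smallest SD of its values (2.19), against medians of 5.34 to 5.39 and SDs of 2.21 to 2.25 on the others. No treatment had a replicate at any time point, so the number of arrays limits the precision, and a difference at 1 time point has no replicate check. Values over the 3 time points are given as mean ± SD of the heme minus vehicle difference (n = 3 time points). No level below 5.37, the median of all values, was shown to be above background. A difference against such a level is given with the bound found by setting that level to 5.37, written as "at least", and has no exact size. Lists of the highest and lowest genes follow measured values, and a gene given a bound has no fixed place in them.

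With heme, Spic, Treml4, Hmox1, Slc40a1, 15 of 28 antioxidant genes and 13 of 26 inflammatory genes rose over the 3 time points. With the 24 h pair left out 4 antioxidant and 3 inflammatory genes did, and Treml4 did not pass (limma, adjusted p = 0.0743). Spic itself (probe set 10371662), required for red pulp macrophages, rose by 3.88 ± 0.47 on the log2 scale, from 5.76 to 9.53 at 6 h, from 6.09 to 10.49 at 24 h and from 6.69 to 10.17 at 72 h (limma, adjusted p = 2.55e-05). These differences correspond to 13.6-fold, 21.1-fold and 11.2-fold. Hmox1 (10572897), heme oxygenase 1, rose by 2.59 ± 0.28 (limma, adjusted p = 8.86e-05), and Slc40a1 (10354374), the iron exporter ferroportin, rose by 2.31 ± 0.50 (limma, adjusted p = 5.65e-04). Treml4 (10445758), a receptor of splenic macrophages and dendritic cells, rose by 3.52 ± 1.16, at least 3.43 (limma, adjusted p = 0.00154), with at least 4.50-fold at 6 h and at least 16.6-fold at 24 h.

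**Figure D1:**
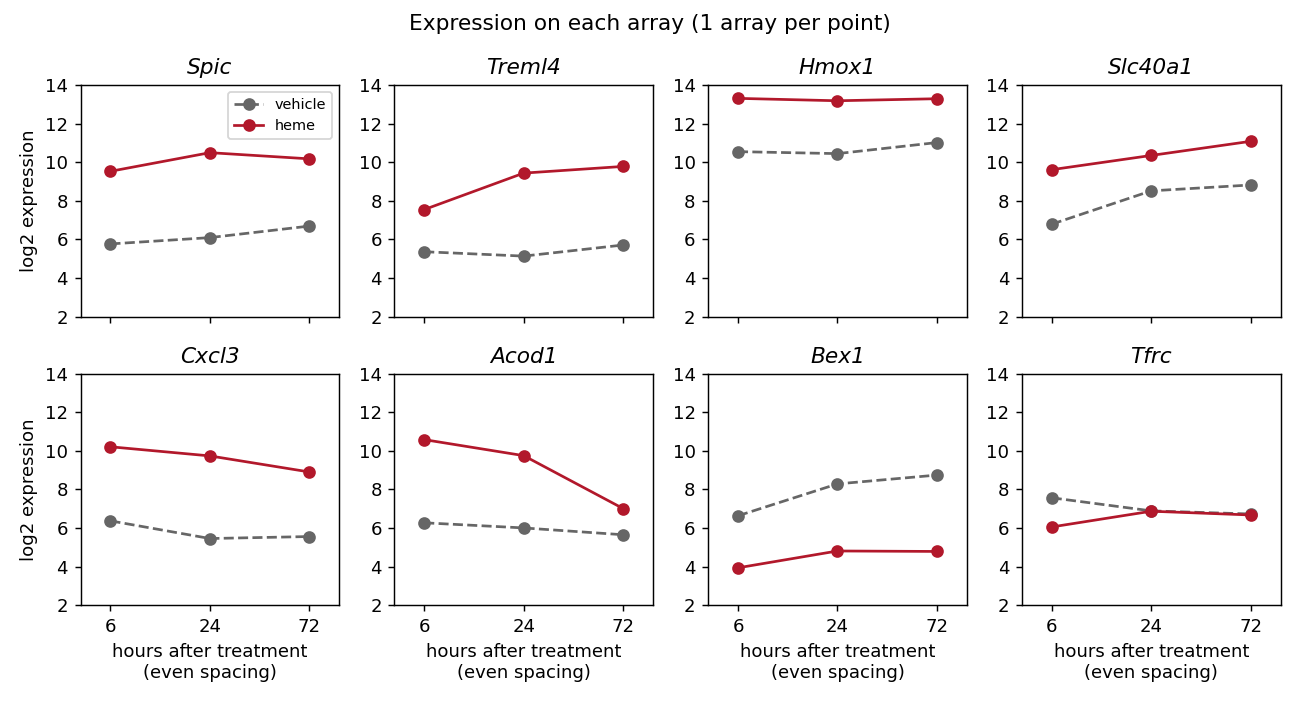
Log2 expression of 8 genes on each array (vertical axis) at 6, 24 and 72 h after treatment (horizontal axis, evenly spaced), with 1 array per point, heme in solid red and vehicle in dashed grey. Spic on heme lay between 9.53 and 10.49 and on vehicle between 5.76 and 6.69, while Tfrc differed by -1.51 at 6 h and by -0.02 at 24 h.

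Of the 10 genes with the largest mean increase among those past the test, Cxcl3, Cxcl2, Saa3 and Il1b belong to the inflammatory list. The neutrophil-attracting chemokines Cxcl3 and Cxcl2 rose by 3.82 ± 0.47 and 2.99 ± 0.44 (limma, adjusted p = 2.55e-05 and 8.86e-05). Acod1, the enzyme that makes itaconate, rose by 3.14 ± 1.57 (limma, adjusted p = 0.0106), with differences of 4.31 at 6 h and 1.36 at 72 h. The acute-phase gene Saa3 and the cytokine Il1b rose by 2.81 ± 0.69 and 2.46 ± 1.06, and the lectin receptor Clec4e rose with differences of 2.97, 3.10 and 1.42 at 6, 24 and 72 h (limma, adjusted p = 0.00364). The chemokine Ppbp rose by 3.47 ± 2.08, at least 3.33 (limma, adjusted p = 0.02), with differences of 1.12 at 6 h and 5.08 at 72 h.

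Among the genes that fell, Bex1 (10606868) showed the largest change, with a measured mean of -3.38 ± 0.64 (limma, adjusted p = 1.43e-04), a decrease of at least 2.51. Its level was 6.63 at 6 h and 8.74 at 72 h on the vehicle arrays and between 3.94 and 4.81 with heme. Slco2b1, an organic anion transporter, fell by 1.53 ± 0.10 (limma, adjusted p = 8.47e-04). Further decreases were seen for Gpx3 (-1.67 ± 0.93), the transcription factor Epas1 (-1.23 ± 0.39), the phospholipase Plcb1 (-1.28 ± 0.27, a decrease of at least 1.01), the secreted factor Ccn3 (-1.25 ± 0.62) and the retinal reductase Dhrs3 (-1.24 ± 0.78). Klra17 fell with a wider spread (-1.75 ± 1.12; limma, adjusted p = 0.0344). Cyp4a12b (limma, adjusted p = 0.0459) was lower by 1.30 at 6 h and 3.39 at 24 h, with both 72 h levels below the level filter. The transcription factor Mkx (limma, adjusted p = 0.00364) was lower by at least 0.78 at 24 h and at least 0.40 at 72 h. Both its 6 h levels lay below the filter. The adjusted p-values of Cyp4a12b and Mkx rest on measured values, with 2 and 4 levels below the filter that have no exact size. A fall at all 3 time points is therefore not shown for either gene.

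In all, 198 of 11516 genes passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 130 up and 68 down, and 1223 had an unadjusted p below 0.05. Each fit used measured values, also where a level lay below the level filter, and calls were not repeated with bounds. After cyclic loess the split was 115 up and 36 down, or 76.2% up in place of 65.7%, and after median-centring 162 up and 117 down, or 58.1% up. Time points are not replicates: with no replicate per group, these p-values measure only how much the heme minus vehicle difference varied between time points. Without the 24 h pair of arrays only 12 genes passed, among them Spic, Hmox1, Slc40a1, Cxcl2, Cxcl3, Saa3, Gclm, Abcc1, Slc7a11 and Bex1. Of the 52 genes named by rule that passed, 42 no longer did, including Treml4 and Acod1 (limma, adjusted p = 0.0743 and 0.255), whereas 521 genes passed without the 6 h pair and 201 without the 72 h pair. Calls were gained by 51 other genes named by rule without the 6 h pair and by 8 without the 72 h pair, where 5 lost theirs. Each fit without a pair had 1 residual degree of freedom. Without the 6 h pair the prior was 46.9 degrees of freedom. Adjusted p-values given without that pair, here and below, therefore reflect little of a gene's own spread.

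Antioxidant genes under NRF2 and BACH1, the activator and the heme-sensing repressor of this response, had a positive median at each time point. Of 28 measured members, 15 rose, 0 fell and 13 did not pass the test, and 18 rose when adjusted over the list alone, but 4 without the 24 h pair. The glutathione synthesis gene Gclm rose by 2.46 ± 0.44, malic enzyme Me1 by 2.27 ± 0.57 (at least 1.80), the exporter Abcc1 by 2.27 ± 0.50 and the cystine transporter Slc7a11 by 1.95 ± 0.28. Median differences of the list were 0.60 at 6 h, 0.96 at 24 h and 0.84 at 72 h, each at percentile 100 of 10000 random lists matched on expression. The list was called up by limma's camera (adjusted p = 6.55e-30), but not with an estimated correlation (adjusted p = 0.50 with an estimated correlation).

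Inflammatory cytokines and NF-kB targets rose in 13 of 26 members, with 0 falling, and 19 rose when adjusted over the list alone; without the 6 h pair 17 rose and 2 fell, and without the 24 h pair 3 rose. Besides the chemokines above, the chemokine Ccl5 rose by 2.36 ± 0.94. Without the 24 h pair Ccl5 and Il1b did not pass (limma, adjusted p = 0.115 and 0.186). Tnf, by contrast, differed by 2.69 at 6 h, 1.09 at 24 h and 0.63 at 72 h and did not pass (limma, adjusted p = 0.0632). It did without the 6 h or the 72 h pair (limma, adjusted p = 0.00104 and 0.0161). The median of the list was 1.23 at 6 h, 1.01 at 24 h and 0.55 at 72 h. Camera called it up (limma, adjusted p = 3.14e-28), and lost the call with an estimated correlation (adjusted p = 0.50 with an estimated correlation).

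Heme and iron handling genes went both ways. Of 33 members, 4 rose and 2 fell, against 8 and 3 when adjusted over the list alone and 7 and 2 without the 6 h pair, 2 and 0 without the 24 h pair and 4 and 1 without the 72 h pair. Hmox1, Slc40a1 and the heme transporter Slc48a1 (1.56 ± 0.44; limma, adjusted p = 0.00364) rose, as did the mitochondrial iron importer Slc25a37, while the heme transporter Flvcr2 and Slco2b1 fell. Biliverdin reductase Blvrb differed by 0.56, 1.89 and 0.80 at 6, 24 and 72 h and did not pass (limma, adjusted p = 0.0589), though it did without the 6 h pair (adjusted p = 1.45e-06). The transferrin receptor Tfrc was lower at 6 h (-1.51), with differences of -0.02 and -0.05 later (limma, adjusted p = 0.566). Bach1, the repressor of Hmox1, differed by 0.14, 0.00 and 0.06 (limma, adjusted p = 0.937). Camera called the list up (limma, adjusted p = 0.00859), and lost the call with ranks (adjusted p = 0.182) and with the correlation between genes estimated (adjusted p = 0.615 with an estimated correlation).

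Of 14 markers of red pulp macrophages, 4 rose, namely Spic, Treml4, Hmox1 and Slc40a1, and 1 fell, the sialic acid receptor Siglec1; counts adjusted over the list alone were 4 and 2, and without the 24 h pair 3 and 0. The hemoglobin receptor Cd163, below the level filter on 5 arrays, did not pass (limma, adjusted p = 0.707) and Adgre1, which encodes F4/80, differed by -0.17, 0.04 and 0.59 (limma, adjusted p = 0.871). Vcam1 stayed below the level filter on every array. The list was called up by camera (limma, adjusted p = 0.00119), and neither with ranks (adjusted p = 0.367) nor with an estimated correlation (adjusted p = 0.50 with an estimated correlation). Its median difference was -0.02, 0.17 and 0.23 at 6, 24 and 72 h.

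**Figure D2:**
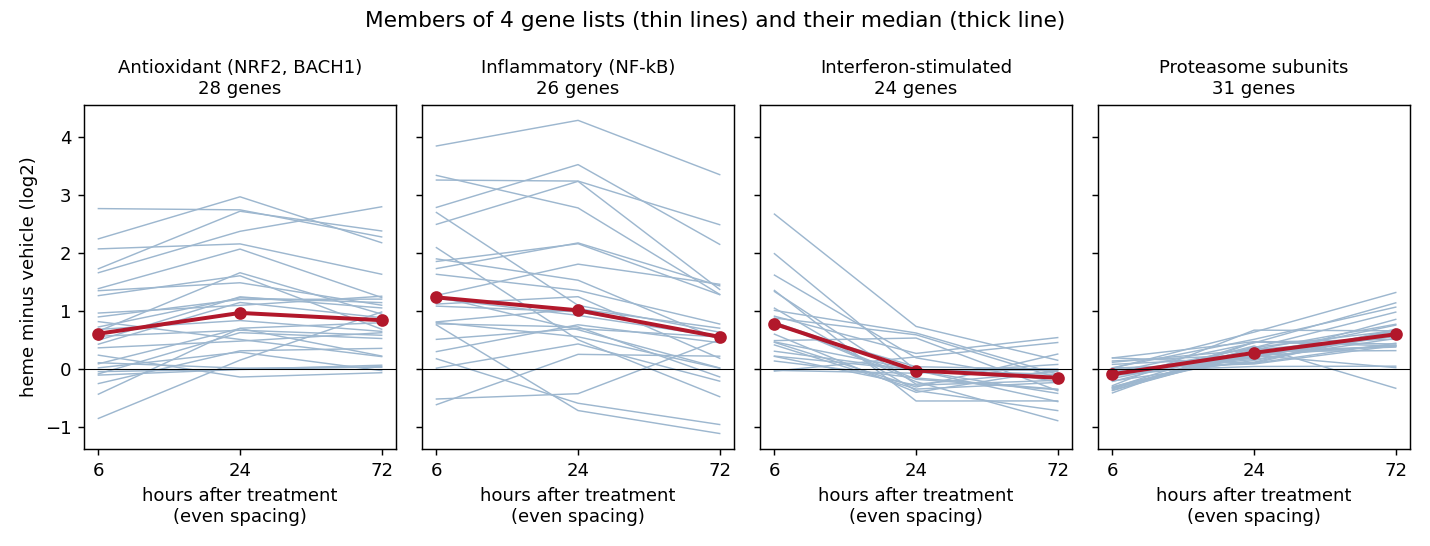
Heme minus vehicle difference in log2 expression (vertical axis) at 6, 24 and 72 h (horizontal axis, evenly spaced) for the members of 4 gene lists, each thin line a gene and the thick line the median. The antioxidant median lay at 0.60, 0.96 and 0.84, the inflammatory median at 1.23, 1.01 and 0.55, the interferon median at 0.77, -0.03 and -0.16, and the proteasome median at -0.10, 0.27 and 0.59.

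Subunits of the proteasome, which degrades ubiquitinated proteins, had medians of -0.10, 0.27 and 0.59 at 6, 24 and 72 h. Of 31 subunits 0 passed the test, 0 when adjusted over the list alone and 5 without the 6 h pair, and 6 had an unadjusted p below 0.05 in limma. Psma5 differed by 1.31 and Psmd1 by 1.06 at 72 h. The list was called up (camera in limma, adjusted p = 1.61e-07), a call lost with an estimated correlation (adjusted p = 0.615 with an estimated correlation). Hypoxia and glycolysis genes had medians of 0.02 (-0.09 after median-centring), 0.34 and 0.37; 1 of 26 rose, the glucose transporter Slc2a1 (0.86 ± 0.19; limma, adjusted p = 0.0187), also 1 adjusted over the list alone; without the 6 h pair 4 rose and 1 fell, and without the 24 h pair 0 rose. That list too was called up (camera in limma, adjusted p = 3.46e-05; adjusted p = 0.57 with an estimated correlation).

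Genes of MHC class II antigen presentation had medians of 0.11 (-0.003 after median-centring), 0.24 and 0.20, with 0 of 13 members past the test, 0 adjusted over the list alone, 2 without the 6 h pair and 4 at an unadjusted p below 0.05 in limma; Cd86 differed by 0.90 at 72 h. Camera called them up (limma, adjusted p = 9.55e-04; adjusted p = 0.50 with an estimated correlation). Interferon-stimulated genes, which act in antiviral defence, had a median of 0.77 at 6 h, -0.03 at 24 h and -0.16 at 72 h (percentiles 100, 24.5 and 0.26 of matched random lists), and 7 of 24 members, among them Cxcl10 (2.67) and Oasl2 (1.61), were at least 2-fold higher at 6 h. Over the 3 time points 0 members passed, 0 also when adjusted over the list alone and 1 without the 72 h pair, 3 had an unadjusted p below 0.05 in limma, and the difference between time points was not tested. The upward camera call (limma, adjusted p = 0.00287; adjusted p = 0.67 with an estimated correlation) was lost without the 6 h pair (adjusted p = 0.13), where the direction was down.

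Lipid, lysosomal and secretory pathway lists were called lower with heme at the preset correlation, and 0 of these 4 with an estimated one. Genes of LXR targets and lipid efflux fell in 4 of 20 members (Fabp4, Plin2, Abcg1 and Pparg, with means from -1.06 to -0.75) and rose in 1, Me1. The other 15 did not pass, among them Abca1 (0.149), Mylip (-0.015), Srebf1 (-0.059) and Apoe (-0.623). A fall of LXR targets as a group is therefore not shown by the members. Adjusted over the list alone, genes of this list fell in 5 members and rose in 1. Their median was -0.27, 0.07 and -0.19, and camera called them down (limma, adjusted p = 0.0139; adjusted p = 0.50 with an estimated correlation), a call lost without the 72 h pair, with ranks and without the time term (adjusted p = 0.0823, 0.0587 and 0.0758). Lysosomal genes had medians of -0.28, -0.20 and -0.13 with 0 of 30 past the test, 0 over the list alone and 8 at an unadjusted p below 0.05 in limma (camera, adjusted p = 2.1e-05; adjusted p = 0.50 with an estimated correlation). Cholesterol synthesis genes had medians of 0.03 (-0.08 after median-centring), -0.24 and -0.29 with 0 of 21 past the test, 0 over the list alone and 3 at an unadjusted p below 0.05 in limma (camera, adjusted p = 0.00859; adjusted p = 0.615 with an estimated correlation). Endoplasmic reticulum chaperones had medians of 0.04 (-0.07 after median-centring), -0.36 and -0.07 with 0 of 20 past the test, 0 over the list alone and 2 at an unadjusted p below 0.05 in limma (camera, adjusted p = 0.0345; adjusted p = 0.617 with an estimated correlation). The cholesterol call was lost without the 72 h pair, the 24 h pair or the time term (camera in limma, adjusted p = 0.469, 0.0531 and 0.384), and the chaperone call likewise (0.235, 0.781 and 0.072) and after cyclic loess (0.139). Without the 6 h pair 2 cholesterol genes, 1 lysosomal gene and 6 lipid genes fell; without the 24 h pair 0 lipid genes fell and 0 rose, and without the 72 h pair 2 fell.

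Cell cycle genes had their lowest medians at 6 h. DNA replication genes had a median of -0.75 at 6 h, -0.07 at 24 h and 0.02 at 72 h (-0.002 after a second quantile normalization). Mitosis genes had medians of -0.54, -0.13 and -0.12. Both lists also fell with time in vehicle, with medians of -1.06 and -1.96 at 72 h against 6 h. Some members then lay near or below the level filter in vehicle, such as Rrm2 (5.385), Prim1 (5.12) and Kif11 (5.22) at 72 h. List medians carry no bounds, so a later decrease in such members could go unseen. Of 27 replication genes 0 passed over the 3 time points, 0 over the list alone, with 4 at an unadjusted p below 0.05 in limma, while 2 of 27 mitosis genes fell, the centromere histone Cenpa (-0.67 ± 0.03) and the kinesin Kif23 (-0.66 ± 0.09), also 2 adjusted over the list alone, but 0 without the 24 h or the 72 h pair. The replication list was called down (camera in limma, adjusted p = 7.22e-05; adjusted p = 0.615 with an estimated correlation), and lost the call without the 6 h pair (adjusted p = 0.376). The mitosis list was called down as well (camera in limma, adjusted p = 2.1e-05; adjusted p = 0.615 with an estimated correlation), a call lost without the time term (adjusted p = 0.121). Oxidative phosphorylation genes had a median of -0.34 at 6 h, 0.08 at 24 h and -0.03 at 72 h and were not called (camera in limma, adjusted p = 0.0522; adjusted p = 0.761 with an estimated correlation), but were called down without the 24 h pair, with no level filter, with ranks and without the time term (camera in limma, adjusted p = 7.32e-04, 0.00502, 0.0116 and 0.0496). Of their 37 members 0 passed, 0 over the list alone, with 0 at an unadjusted p below 0.05 in limma.

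Other pathway lists were not called by camera. In ATF4 targets 2 of 27 rose, Slc7a11 and its partner Slc3a2 (0.77 ± 0.25), also 2 adjusted over the list alone, with limma's camera at an adjusted p of 0.144. The death receptor Fas, 1 of 18 p53 targets, rose by 1.03 ± 0.41, also 1 adjusted over the list alone, and the list had an adjusted p of 0.328 in limma's camera. The zinc importer Slc39a4, 1 of 10 genes of metallothioneins and zinc transport, rose by 1.55 ± 0.99, with 1 up and 1 down adjusted over the list alone, beside a list adjusted p of 0.89 in limma's camera. Heat shock (adjusted p = 0.825), alternative activation (0.216), immediate early (0.799) and cytosolic ribosomal protein genes (0.799) were not called either by limma's camera. Of their 18, 14, 19 and 35 members 0 passed, with 1, 0, 2 and 0 up when adjusted over the list alone. At an unadjusted p below 0.05 in limma there was 1 heat shock gene up, 2 alternative activation genes up and 2 down, 2 immediate early genes up and 4 down, and 0 ribosomal protein genes. Without the 6 h pair 4 alternative activation genes rose and 1 fell, 3 ATF4 targets rose and 1 fell, 1 p53 target rose and 1 fell, and 2 immediate early genes and 1 heat shock gene rose. Without the 24 h pair 1 ATF4 target rose and 0 p53 or zinc genes did. Without the 72 h pair 0 zinc genes and 1 immediate early gene rose, and 1 alternative activation gene fell.

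Markers of other cell types also differed. Of 17 neutrophil lineage genes, 2 rose, Chil1 (1.91 ± 0.97) and Csf3r (1.13 ± 0.25), with 5 adjusted over the list alone, 8 without the 6 h pair and 0 without the 24 h pair. Their median was 0.05 at 6 h (-0.11 after median-centring), 0.69 at 24 h and 0.12 at 72 h, and at 24 h 7 of them were at least 2-fold higher. Camera called the list up (limma, adjusted p = 2.41e-06; adjusted p = 0.57 with an estimated correlation). Dendritic cell genes rose in 1 of 17 members, the chemokine receptor Ccr7 (1.16 ± 0.59), with 6 up and 1 down adjusted over the list alone and 3 up without the 6 h pair; their medians were 0.43, 0.12 and -0.03 (camera in limma, adjusted p = 0.00859; adjusted p = 0.615 with an estimated correlation). That call was lost without the 24 h pair and with ranks (camera in limma, adjusted p = 0.0732 and 0.0861). Monocyte genes rose in 2 of 14, Treml4 and Vcan, and fell in 1, Ace, with 2 and 2 over the list alone (camera in limma, adjusted p = 0.134, 0.615 with an estimated correlation and 0.005 without the 6 h pair, when 4 rose). General macrophage genes rose in 1 of 24, Cd14 (1.09 ± 0.26), and fell in 1, Pros1 (-0.78), with 3 and 5 over the list alone and 3 and 3 without the 6 h pair (camera in limma, adjusted p = 0.2). Without the 24 h pair 0 dendritic cell, monocyte or macrophage genes passed, and without the 72 h pair 2 dendritic cell genes rose and 2 macrophage genes rose and 2 fell.

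Of 6 megakaryocyte genes, 2 rose, Ppbp and Pf4 (1.88 ± 0.79), while Vwf differed by -1.07 at 72 h (camera in limma, adjusted p = 0.0681, 0.57 with an estimated correlation and 4.75e-05 without the 6 h pair); over the list alone 2 rose and 1 fell. Stromal genes fell in 1 of 15, Fstl1 (-1.04 ± 0.29), also 1 over the list alone (camera in limma, adjusted p = 0.448, 0.831 with an estimated correlation and 0.0102 without the 6 h pair, when 2 rose and 1 fell). Of 6 eosinophil and 7 B cell genes 0 passed, with 1 and 2 down over the list alone and the same numbers at an unadjusted p below 0.05 in limma. Their camera adjusted p values in limma were 0.132 and 0.825, and the eosinophil list was called without the 24 h pair (adjusted p = 0.00303; 0.67 with an estimated correlation). Without the 6 h pair 1 eosinophil gene rose and 1 fell, 2 B cell genes fell, and 2 megakaryocyte genes rose and 1 fell; without the 24 h pair 0 megakaryocyte and 0 stromal genes passed. Mast cell and basophil, erythroid, and T and NK cell lists kept 2, 1 and 3 genes and were not tested as lists. Altogether 16 of 30 tested lists were called, 10 up and 6 down, and 0 with an estimated correlation, where 1 list had an unadjusted p below 0.05 in limma's camera. The MHC class II and LXR lists lost their calls there with estimated correlations of -0.057 and 0.001, below the preset 0.01. For these lists a lost call therefore does not by itself show that correlation between genes accounts for it. Every other called list had an estimate above 0.01, from 0.047 (red pulp macrophage) to 0.614 (interferon) and 0.793 (proteasome). There correlation between genes may account for the lost call, and the camera values at the preset correlation may be too small.

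**Figure D3:**
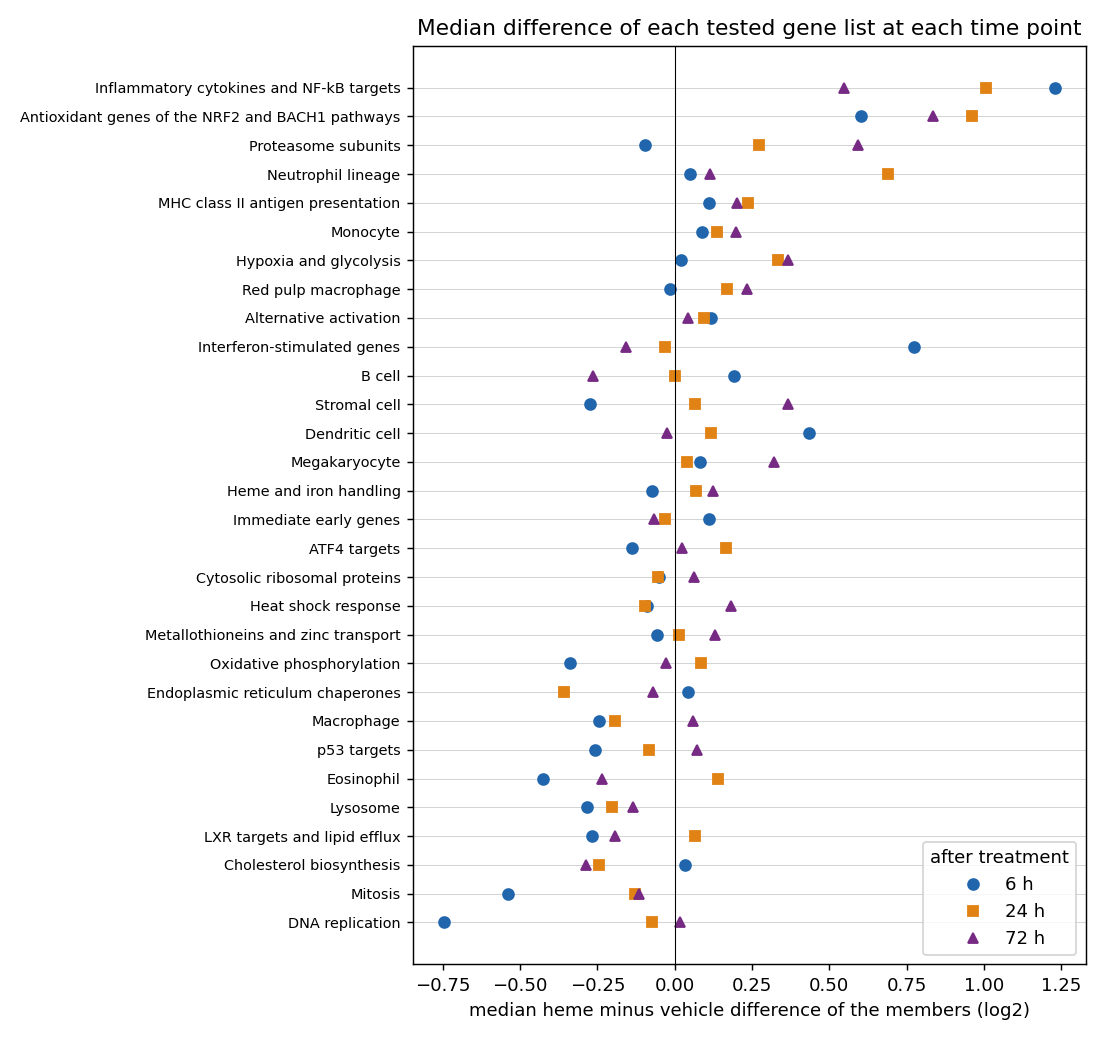
Median heme minus vehicle difference in log2 expression (horizontal axis) of each of 30 gene lists (vertical axis), with 1 symbol per time point after treatment. The inflammatory list reached 1.23 at 6 h and the DNA replication list -0.75 at 6 h.

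At 6 h inflammatory mediators, Spic, Hmox1 and Slc40a1 were among the highest genes. The 10 highest genes were Acod1 (19.8-fold), Cxcl3 (14.3-fold), Spic (13.6-fold), Il1b (10.1-fold), Cxcl2, Clec4e, Slc40a1, Saa3, Hmox1 (6.77-fold) and Tnf (6.47-fold). By measured value the 10 lowest were Bex1 (lower by at least 1.26, which does not secure it a place), Dhrs3 (-1.91), Slco2b1 (-1.65), Tmem273, the replication helicase subunit Mcm6 (-1.64), the cell cycle inhibitor Cdkn2c, Kctd12b, Tfrc (-1.51), Tmem37 and Sh2d1b1 (-1.44). At least 2-fold differences were seen for 188 genes, 111 higher and 77 lower with heme. The median difference of all genes was -0.10 as deposited and -0.22 after median-centring, which turned the split to 86 higher and 159 lower, 35.1% higher in place of 59%. Relative to the median of all genes, the inflammatory list stood at 1.33, the interferon list at 0.88, the antioxidant list at 0.71, the DNA replication list at -0.64 and the oxidative phosphorylation list at -0.24.

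At 24 h Spic, Treml4 and the chemokines Cxcl3, Ppbp, Cxcl2 and Ccl5 were among the highest genes. By measured value the 10 highest genes were Spic (21.1-fold), Treml4 (at least 16.6-fold), Cxcl3 (19.4-fold), Ppbp (at least 13.9-fold), Acod1, Saa3, Cxcl2, Ccl5 (9.38-fold), the protease inhibitor Stfa2 (at least 6.35-fold; limma, adjusted p = 0.325 over the 3 time points and 3.94e-06 without the 6 h pair) and Clec4e (8.60-fold), and the bound of Stfa2 does not secure it a place. The 10 lowest were Bex1 (lower by at least 2.91), Cyp4a12b (-3.39), Cyp4a12a (lower by at least 3.08), Klra17 (-2.35), Tnfsf8 (lower by at least 1.49, not secure in its place either), Cd28, Pdgfc, Fcgr4 (-1.80), Fcrls and Ifi207. Without the 6 h pair Stfa2 passed although both its 72 h levels lay below the filter, in a fit where its own spread counted for little. Cyp4a12a and Cyp4a12b are near-identical genes, so their probe sets can share signal. In all, 220 genes differed at least 2-fold, 164 higher and 56 lower.

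At 72 h the largest differences with both levels above the filter were in Ppbp (33.9-fold), the scavenger receptor Marco (28.8-fold) and Treml4 (16.8-fold). Spic, Cxcl3, the chemokine Cxcl5 (at least 2.46-fold), the glutathione transferase Gsta3 (at least 6.66-fold), the interleukin 36 gamma gene Il1f9 (at least 3.83-fold), the lectin receptor Clec4a1 (7.42-fold) and Me1 (at least 4.64-fold) completed the 10 highest by measured value, among which the bounds of Cxcl5, Gsta3, Il1f9 and Me1 secure no place. Cxcl5, from 3.06 on vehicle to 6.67 on heme, lay below the level filter on the other 5 arrays. Marco, Cxcl5 and Gsta3 did not pass over the 3 time points (limma, adjusted p = 0.055, 0.228 and 0.115). They did without the 6 h pair (limma, adjusted p = 8.65e-15, 4.56e-10 and 1.81e-17), and Marco also without the 72 h pair (adjusted p = 0.0186). Those fits had 1 residual degree of freedom, and without the 6 h pair the spread of each gene counted for little. By measured value the 10 lowest were Bex1 (lower by at least 3.37), Gpx3 (-2.69), Klra17 (-2.45), Ifi27l2a (-2.18), Slamf7 (-2.13), Mkx (lower by at least 0.40, which does not secure it a place), Ccn3, H2-T24, the bridging protein Mfge8 (-1.71) and Hamp (-1.70), which encodes the iron hormone hepcidin. There were 214 genes at 2-fold or more, 144 higher and 70 lower.

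The 2-fold genes overlapped between time points. Higher at all 3 were 38 genes, against 0.02 expected from independent lists, and 5 were lower at all 3 (0.002 expected). Pairwise, 59 higher genes were shared by 6 and 24 h, 40 by 6 and 72 h and 86 by 24 and 72 h (1.58, 1.39 and 2.05 expected). Across genes, which are not independent replicates, differences correlated with r = 0.435 between 6 and 24 h, 0.20 between 6 and 72 h and 0.44 between 24 and 72 h, and by rank with Spearman's rho = 0.262, 0.056 and 0.153. A 2-fold difference in opposite directions was seen in 1 gene, the leukotriene synthesis gene Alox5, named after its values were seen, which was lower at 6 h and higher at 72 h (1.39).

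Vehicle cultures gave the background of change with time. By measured value the 5 lowest genes at 72 h against 6 h were the chemokine Ccl17 (-5.63), the neutrophil genes S100a9 (-4.83) and Ngp (lower by at least 4.46) and the protease inhibitors Stfa2 (at least 3.29) and Stfa3 (at least 3.13), whose bounds secure them no place, and the 5 highest were the lipid carrier Apoe (4.16), the receptor Adgre4 (at least 3.44), Cd300ld (3.04), Saa3 (2.83) and the proton-sensing receptor Gpr65 (at least 2.61). Mitosis genes had a median of -1.96, with 24 of 27 at least 2-fold lower, DNA replication genes of -1.06 (14 of 27), cholesterol synthesis genes of -1.01 (11 of 21) and neutrophil genes of -0.88 (8 of 17, with 2 at least 2-fold higher, Csf3r at 2.23 and Chil1 at 1.32). General macrophage markers had a median of 0.34, with 3 at least 2-fold higher and 1 lower, and red pulp macrophage markers of 0.41, with 2 higher and 0 lower. In all, 490 genes differed at least 2-fold, 162 higher and 328 lower at 72 h, and between 6 and 24 h 186 genes did, 41 higher and 145 lower. Spic differed by 0.93 and Hmox1 by 0.47 between the vehicle arrays of 6 and 72 h, and Slc40a1 by 2.03.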

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

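Tests of explanations below were all chosen after the results they bear on had been seen; the differences between time points listed here were not tested, since each rests on 1 array per group. A result is listed where a named gene differed by at least 1.5-fold in opposite directions at different time points, where a list's median lay in opposite tails of random lists with opposite signs, or where probe sets outside the gene comparisons differed.

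Slamf7 was higher with heme at 6 h (0.90) and lower at 72 h (-2.13). Arg1, the enzyme arginase 1, was lower at 6 h (-0.77) and higher at 72 h (2.38). Acta2 went from -0.60 at 6 h to 1.61 at 72 h. Car2 measured 0.76 at 6 h and -0.66 at 72 h, but both 6 h levels lay below the level filter and the decrease at 72 h is at least 0.13, so no change of direction is shown. Interferon-stimulated genes had a median of 0.77 at 6 h and -0.16 at 72 h. Cholesterol synthesis genes went from 0.034 at 6 h to -0.29 at 72 h and endoplasmic reticulum chaperones from 0.043 at 6 h to -0.36 at 24 h; both 6 h values were below 0 after median-centring (-0.08 and -0.07). Oxidative phosphorylation genes stood at -0.34 at 6 h and 0.084 at 24 h.

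Of 7312 probe sets without a single gene name that passed the level filter, 8 were at least 2-fold higher with heme at all 3 times and 1 was lower. A further 19 reached 2-fold at each time with mixed signs, and equal chances of either sign would give 7 of the 28 with 1 sign throughout.

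DNA replication genes and oxidative phosphorylation genes had their lowest medians with heme at 6 h. A level-dependent distortion of the 6 h heme array, which had the narrowest spread of values, would leave medians near 0 once the trend with level is removed. After cyclic loess they were -0.77 (quartiles -0.92 and -0.53) and -0.27 (quartiles -0.38 and -0.16), against -0.75 and -0.34 before. Cyclic loess left the median 6 h difference of all genes at -0.08. Relative to that median the lists stood at -0.69 and -0.19, against -0.64 and -0.24 before. A 6 h heme culture at the stage of the 24 h vehicle culture would need oxidative phosphorylation genes to be lower in vehicle at 24 h, where their change was 0.006 (quartiles -0.17 and 0.10). For replication genes that explanation is left open. The 41 genes higher in vehicle at 24 h by a median of 1.195 had a median of -0.05 with heme at 6 h, yet went both ways (quartiles -0.46 and 0.64). Neutrophil genes, at -0.75 in vehicle, had 0.05, but heme may act on these cells itself. An effect of heme on cycling cells may also account for the lower replication genes and was not tested.

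Ppbp and Pf4 were 33.9-fold and 5.27-fold higher with heme at 72 h, and both are abundant in platelets. Platelets or megakaryocytes in the heme culture would bring their other transcripts, and the 7 other markers measured had a median difference of -0.30 (from -1.07 to 0.48). Treml1 and Vwf, the brightest of the 7 on the heme array at 72 h (7.83 and 7.55), differed by 0.17 and -1.07. They alone lay above the level filter on both 72 h arrays. The -0.30 of Gp5 and the 0.48 of Itga2b (at least 0.18) involve a level below it and have no exact size. Only 3 of the 7 reached the filter on the heme array, and a small share of platelets could go unseen in dim markers. Platelets and expression by the cultured myeloid cells cannot be told apart on these values.

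Neutrophil genes were higher with heme at 24 h, when their median in vehicle was -0.75 against 6 h. More neutrophil lineage cells in the adherent fraction would raise all members, and slower loss of transcripts in the same cells only those that decline in vehicle. The 8 members that were at least 2-fold lower in vehicle at 72 h than at 6 h had a median 24 h difference of 1.89 (from 0.37 to 2.62), and the 6 others above the level filter at 24 h 0.25 (from -0.29 to 2.90), so the 2 causes cannot be told apart. For Lcn2 and Chil1 at 72 h (2.49 and 1.89) more such cells stay an open explanation. The 9 other members above the level filter on either 72 h array had a median of 0.431 (quartiles 0.03 and 0.85), with Csf3r (1.42) and S100a9 (1.05) at least 2-fold higher and Camp at 0.03. Over all 15 other members the median was 0.027, with 8 of 15 higher. S100a8 and S100a9 are also expressed by monocytes.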

How the results depend on the processing

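Leaving out pairs for counts within lists and gene families, list medians after median-centring or a second quantile normalization, and the tests on other splits were chosen after the data were seen, the other alternatives before. Counts at 6, 24 and 72 h moved with the threshold: 1180, 752 and 793 genes at 1.5-fold and 24, 49 and 34 at 4-fold; the offset of 16 left 122 at 6 h. At 6 h the threshold also turned the split, with 387 higher and 793 lower at 1.5-fold (32.8% higher), 59% higher at 2-fold and 95.8% at 4-fold. For vehicle, 72 h against 6 h, 1360 genes passed 1.5-fold, 87 passed 4-fold and 324 were counted with the level filter at the 75th percentile, where fewer genes were examined. Over the 3 time points 18 genes passed in limma without the time term, where differences between time points stay in the residual, and 12 to 521 with 1 time point left out. The cause of the low count without the 24 h pair was not tested; without the 6 h pair the estimated prior degrees of freedom grew from 7.17 to 46.9, so that each gene's own spread counted for less. The remaining alternatives gave 151 to 279 genes, with 0 sign changes among those of the 198 that were tested in each. Camera called 0 lists with an estimated correlation, with 1 at an unadjusted p below 0.05, and 13 to 17 in the other alternatives; the interferon list lost its call without the 6 h pair, with the direction down (camera in limma, adjusted p = 0.13), against 2.24e-07 without the 72 h pair, the cause being the interferon median, which was above 0 at 6 h alone. Of list medians outside the middle range of random lists, 2 changed sign with the genes kept, MHC class II at 6 h (-0.006 with the 75th percentile filter) and B cell at 72 h (0.004 with no filter). Median-centring, which lowered the 6 h differences, turned 6 at 6 h: hypoxia (-0.093), cholesterol (-0.08), chaperones (-0.071), monocyte (-0.025), MHC class II (-0.003) and immediate early genes (-0.003). Among 3171 planned checks on single lists and named genes, 2906 were counted as unchanged, 156 as losing the call, 106 as gaining it and 3 as turned. The unchanged include results called neither before nor after, such as Tfrc without the 24 h pair, so their number does not measure how well calls held. Only results called at first could count as turned. Changes of sign in results not called at first are within the other counts, such as Mcm6 without the 6 h pair (0.236 against -0.389).

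Of the 10 splits of the 6 arrays into 3 and 3, only the 4 that part all 3 pairs are comparable under a fit with time as a block, too few for a share under 0.05. In limma the real one gave 198 genes and the highest other 0 (149 to 563 at an unadjusted p below 0.05), so 1 split reached the real count. Each other comparable split swaps the treatments within 1 pair. A heme difference shared by the time points then enters its residual, which lowers its count. The 0 is therefore no separate support for the 198 genes. For lists called by camera at the preset correlation, the real one gave 16 and the highest other 10. Among all 10 splits the highest other gave 12 lists, so many calls at the preset correlation can arise without a split by treatment.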

Other observations

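The tests of gene families and of time course below were chosen after the results had been seen. C-type lectin receptors, several of which sense microbes and damaged cells, were over-represented among the 198 genes past the test. Of 18 measured Clec genes 4 rose, Clec4e, Clec4d, Clec4a1 and Clec5a (one-sided Fisher's exact test, adjusted p = 0.0356 over 183 families of genes with a shared name stem), and all 4 were higher with heme at each time point. Of the 12 genes past the test without the 24 h pair 0 were Clec genes, and without the 72 h pair 3 did (one-sided Fisher's exact test, adjusted p = 0.129). Clec4d was higher by 1.17, 2.42 and 1.81 at 6, 24 and 72 h. Of 9 Cxcl chemokines 3 rose, Cxcl1, Cxcl2 and Cxcl3 (one-sided Fisher's exact test, adjusted p = 0.0356), and 2 without the 24 h pair (adjusted p = 0.00653). Genes with the Slc stem passed in 11 of 202 (one-sided Fisher's exact test, adjusted p = 0.0448), 9 of them up, such as the carnitine and ergothioneine transporter Slc22a4 and the hexose transporter Slc2a6, and 2 down, the transporter Slc46a3 and the adaptor Slc9a3r2, which is not itself a carrier. Only 2 Slc genes passed without the 24 h pair, and 10 without the 72 h pair (one-sided Fisher's exact test, adjusted p = 1.0 and 0.129). Interleukin genes passed in 4 of 34 (one-sided Fisher's exact test, adjusted p = 0.12). Neighbouring genes of a family are not independent of each other, which this test ignores.

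Other genes that rose, named here after their values were seen, were the Notch ligand Jag1 (at least 1.44, 1.77 and 2.44 at 6, 24 and 72 h; limma, adjusted p = 5.65e-04), the lipid-presenting molecule Cd1d1 (1.04, 1.68 and 2.26; limma, adjusted p = 0.0058), the aldo-keto reductase Akr1b8 (at least 0.56, 1.38 and 1.66; limma, adjusted p = 0.00364) and the complement protease C1ra (1.19 at 72 h; limma, adjusted p = 0.0285). Cd1d1, Akr1b8 and C1ra did not pass without the 24 h pair (limma, adjusted p = 0.169, 0.162 and 0.393), nor did C1ra without the 72 h pair (adjusted p = 0.0871). The ferritin chains Fth1 and Ftl1, whose protein is known to be set largely by translation, differed by 0.10 and 0.23 at 6 h and by 0.03 and -0.07 at 72 h (limma, adjusted p = 0.953 and 0.994).

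From 6 to 72 h, the heme minus vehicle difference of inflammatory genes changed by a mean of -0.73 ± 0.85 (SD over 26 genes), lower in 21 of 26, and that of antioxidant genes by 0.22 ± 0.56 (SD over 28 genes), lower in 11 of 28. The means differed by 0.945. Whether the time courses of these lists differ beyond chance is left open: the comparison was picked from the medians it compares, genes of a list are correlated (estimated correlation 0.445 in the inflammatory and 0.255 in the antioxidant list), and each time point has 1 array per group.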
